A study of Mus musculus with 6 samples.

How the data were processed

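RNA-seq libraries were made from mouse NPC subclones carrying an auxin-inducible degron on SPEN, per the labels. The cells grew in N2B27 medium with EGF and FGF at 10 ng/ml each on 0.1% gelatin and received auxin at 500 uM for 0, 24 or 48 h. RNA with a RIN score above 9 went into TruSeq RNA kit v2 libraries that were sequenced as read pairs of 100 bases, per the labels' protocols. The deposited values are raw counts of read pairs per gene, which the authors made with featureCounts 1.6.1 over exons, reversely stranded (-s 2), on the Ensembl release 92 annotation of GRCm38 (mm10), per the file headers. The headers name alignments in a folder called STAR and marked as merged and free of duplicates, and the submitters' processing notes also name R 3.4.2 and DESeq2. The exon length of each gene in bp is deposited beside the counts, per the file headers.

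Each file held 53801 genes, of which 53620 matched a symbol by Ensembl identifier and 181 did not. The strand setting was checked on 156 genes whose exons lie inside exons of a strongly expressed gene on the opposite strand (at least 6000 counts). Their median ratio of counts per bp to that gene was 0.0012, and 2 of the 156 pairs reached 0.5, so antisense genes were kept apart. Every library had 0 counts on the mitochondrial chromosome, so the list of 13 mitochondrially encoded genes was not tested. Total counts per library ran from 24603816 (untreated, clone 30) to 43008978 (24 h, clone 31), and a floor of 3 counts corresponded to 0.122 CPM in the smallest library and 0.070 CPM in the largest. Floors and intervals cover counting error only.

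Groups were the 3 auxin times with n = 2 each. Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust, 2-sided) on all 6 libraries with treatment group as the term, TMM normalization and filterByExpr, which kept 16007 genes (15492 filtered by clone), at a Benjamini-Hochberg adjusted p of 0.05. The 3 contrasts were 24 h against untreated, 48 h against untreated and 48 h against 24 h, with a joint test of both auxin terms. The clones were compared with treatment group and clone as terms. Standard errors of edgeR values are the log2 change divided by the square root of F, and those of DESeq2 values are the ones DESeq2 gives. Libraries of the same number come from the same subclone, per the sample titles. Their deviations from the group means correlated across genes at 0.80 (untreated and 24 h), 0.58 (untreated and 48 h) and 0.71 (24 h and 48 h), so the clone pairs them. The fit with the clone as a block is given beside each result that it changes. The common biological coefficient of variation was 0.271 without the block and 0.121 with it, on 3 and 2 residual degrees of freedom. CPM values are normalized by TMM, and principal components used log2 CPM with a prior count of 2.

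The 24 fixed lists cover X escape, the X-inactivation centre, SPEN partners, Notch targets, NPC identity, neuron, astrocyte, oligodendrocyte, pluripotency, mesenchymal and endoderm markers, mitosis, S phase, p53, aryl hydrocarbon receptor, stress, interferon, immediate early, EGF and FGF feedback through ERK, cholesterol, hypoxia, germline, imprinted and mitochondrially encoded genes. They and all X-linked genes were tested with limma 3.58.1 camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. The contrasts, main fits, lists, most alternatives and the rule for named genes were fixed before the data were examined. That rule takes the 10 largest rises and falls at each time against untreated (the 5 largest between times and between clones) among called genes with at least 5 CPM on average that moved the same way in both clones or at all times, filled from the blocked fit, with Spen, Xist and up to 4 members per list by smallest p. Some genes that the rule names are not reported here.

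Alternatives were DESeq2 size factors, upper-quartile scaling and total counts, a filter at 1 CPM or none, DESeq2 1.42.0, limma voom, the clone as a block, the 4 libraries of the groups compared, and leaving out each library. Chosen after the data were seen were thinning every library to the lowest total, removal of each library's trend on GC content and length, voom, other scalings and the 4 libraries with the block, DESeq2 with the block between 24 h and 48 h, and naming of 24 h genes from DESeq2 with the block. GC content from GENCODE vM21 on GRCm38 was known for 15987 of 16007 genes (99.9%). In the auxin comparisons, lists with 1 library left out were tested on treatment group alone, where the clones are then unbalanced between groups. Shared untreated libraries were modelled with 10 simulations of unchanged groups.

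Tests were run on simulated data with 100 genes changed 2-fold and 100 changed 1.5-fold. At 24 h (15797 genes tested) edgeR recovered 0% of both on treatment group alone; with the block it recovered 89% and 36% with 12 of 137 calls false (8.8%), and DESeq2 with the block 93% and 53% (12.6% false). At 48 h (15768 genes) edgeR recovered 0% on treatment group alone, and 92% and 47% with the block (14.7% false). For 48 h against 24 h (15774 genes) it recovered 0% on treatment group alone, and 90% and 33% with the block (10.2% false). Between the clones (15470 genes) it recovered 96% and 75% (13.6% false). A count of 0 on treatment group alone therefore sets no limit on the number of changed genes, and false calls exceeded the 5% aimed for. The simulated clones responded alike to auxin, so recovery with the block may be lower in the real libraries. A count of 0 with the block at 24 h therefore sets no such limit either. Allelic expression was not analysed here.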

Results

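RNA was sequenced from mouse neural progenitor cells (NPCs), the dividing stem-like cells of the neural lineage, derived in culture from embryonic stem cells of the hybrid background BL/6J x CAST-EiJ. The cells carry an auxin-inducible degron on SPEN, a tag through which the plant hormone auxin triggers breakdown of the tagged protein. SPEN is a large RNA-binding repressor that Xist RNA recruits to the X chromosome being silenced, and it also acts as a corepressor of Notch target genes. There were 2 NPC subclones, clone 30 and clone 31, each sampled untreated, after 24 h and after 48 h of auxin at 500 uM, which gives 6 libraries in 3 groups with n = 2 per group. Total counts of clones 30 and 31 were 24603816 and 40257256 untreated, 39637361 and 43008978 at 24 h, and 29668494 and 27628297 at 48 h. Counts hold both parental alleles together, so expression from the active and the inactive X chromosome was not separated. Principal component 1 of log2 CPM (47.3% of variance) and component 2 (37.2%) parted the clones and the 48 h libraries rather than the 24 h libraries from their untreated partners.

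Spen RNA (ENSMUSG00000040761, chromosome 4, 141467890 to 141538597, mm10) was higher in every auxin library than in the untreated library of its clone. It stood at 104 ± 16.5 CPM (SD, n = 2) untreated, 196 ± 31.3 CPM at 24 h and 229 ± 41.9 CPM at 48 h. The degron acts on the protein, so this RNA does not measure depletion of SPEN. At 24 h the log2 change was 0.91 ± 0.08 (SE) with the clone as a block, and both clones gave 0.91. That change passed in DESeq2 with the clone as a block (adjusted p = 1.96e-09) and not in edgeR (adjusted p = 1 on treatment group alone, 0.204 with the block). At 48 h it was 1.14 ± 0.09 (edgeR adjusted p = 0.139 on treatment group alone, 0.0238 with the block), and from 24 h to 48 h it was 0.23 (edgeR adjusted p = 0.522, 0.0948 with the block).

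Xist, the long noncoding RNA that coats and silences the inactive X chromosome (X, 103460375 to 103483217), followed a similar course. It went from 783 ± 111 CPM (SD, n = 2) untreated to 1100 ± 99.1 CPM at 24 h and 1580 ± 345 CPM at 48 h. Its log2 change was 0.49 ± 0.12 at 24 h (edgeR adjusted p = 1, 0.663 with the block; DESeq2 with the block 0.0687). At 48 h Xist was higher by 1.0 ± 0.12 with the clone as a block (edgeR adjusted p = 0.139 on treatment group alone, 0.0238 with the block). Between 24 h and 48 h the blocked change was 0.51 (edgeR adjusted p = 0.202, 0.0326 with the block). The plot of Spen and Xist CPM by time shows each clone moving the same way.

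**Figure D1:**
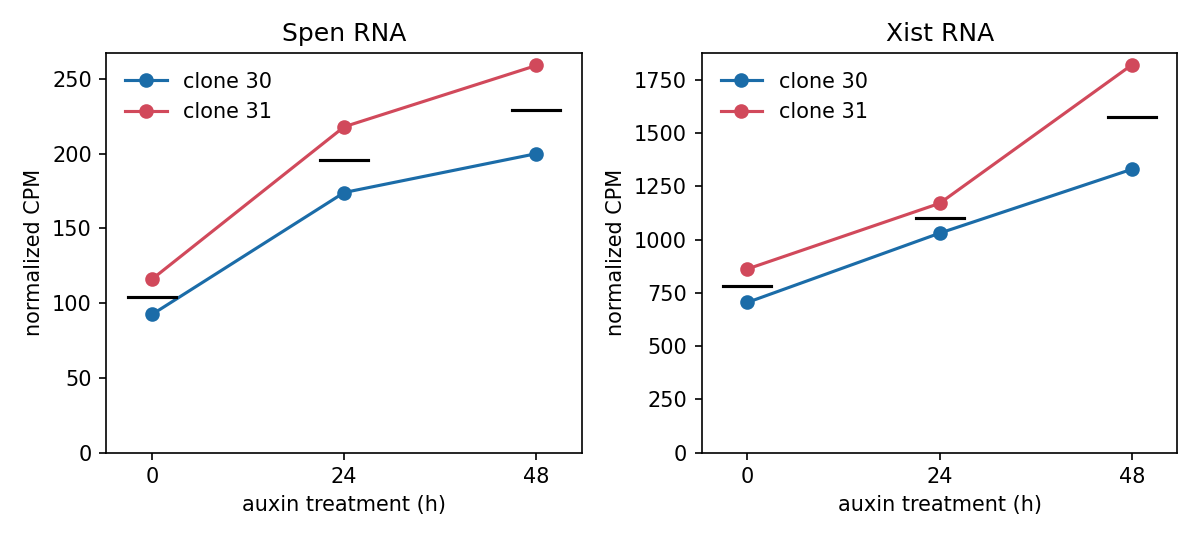
Normalized CPM of Spen (left) and Xist (right) against hours of auxin, 1 point per library joined by clone, with black bars at the mean of the 2 libraries. Spen lies at 104 CPM untreated, 196 CPM at 24 h and 229 CPM at 48 h on average, and Xist at 783, 1100 and 1580 CPM.

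The comparison of 24 h of auxin with untreated cells asks what changes in NPCs within a day of auxin, which is meant to trigger SPEN loss. Among the genes that were lower, Lrrc4c, a synaptic adhesion gene (chromosome 2, 96318169 to 97631666), went from 24.1 ± 15.5 to 7.67 ± 5.95 CPM (SD, n = 2), and Tnr, which encodes the matrix protein tenascin R, from 10.3 ± 1.95 to 3.12 ± 0.279 CPM. Their log2 changes with the clone as a block were -1.72 ± 0.20 and -1.71 ± 0.25 in DESeq2 (adjusted p = 1.56e-14 and 1.33e-08). Rph3a, a vesicle gene, Ctnna2, an adhesion gene, and Erbb4, a neuregulin receptor gene, were lower by -1.92, -1.50 and -1.36 in the same test. Negr1, Sez6, Cadm2 and Megf11, further surface or adhesion genes, were lower by -1.19, -1.24, -1.15 and -1.14. No list of such genes was tested, and the neuron list was not called at 24 h, with 8 of 14 members below 0 and 6 above, 0 of them called (camera adjusted p = 0.341, 0.388 with the block). Among the genes that were higher in that test, Hopx, a homeodomain-only gene, changed by 1.27 ± 0.26, Srxn1, an antioxidant gene, by 0.82 ± 0.18 and Trim16 by 0.77 ± 0.17. Svop, Dusp15, Ptprv, Trim9, Tagln2 and Dyrk3, which act in vesicles, signalling, ubiquitination, cytoskeleton and kinase pathways, completed the list of largest rises with 0.70 to 1.11.

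These genes were called by DESeq2 with the clone as a block, a choice made after their values were seen. The edgeR test called 0 genes at 24 h on treatment group alone (240 at an unadjusted p under 0.05) and 0 with the clone as a block (988 unadjusted). On treatment group alone DESeq2 called 6 genes and limma voom 0; with the block DESeq2 called 41 (13 higher, 28 lower) and limma voom 0. With the block, edgeR called 258 genes without the 48 h library of clone 30, 263 without that of clone 31, 1 without the untreated library of clone 31, and 140 with the 4 libraries of these groups alone.

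At 24 h the p53 target list, genes switched on by the DNA damage regulator p53, lay above 0 in 14 of 14 members with a median log2 change of 0.34. None of the 14 passed over all genes tested, while 8 were higher and 0 lower adjusted over the list alone in the blocked fit, among them Phlda3 (0.48 ± 0.10), Fas (0.70 ± 0.16) and Sesn2 (0.39 ± 0.10). The list passed limma's camera on treatment group alone (adjusted p = 0.000330), with adjusted p = 0.922 with an estimated correlation. Within clone 30 its median was 0.41 and within clone 31 it was 0.23. On treatment group alone its median was -0.03 without the 24 h library of clone 30 and 0.11 without the untreated library of clone 31. It was 0.68 without the 24 h library of clone 31 and 0.65 without the untreated library of clone 30. Those fits hold no clone term, and leaving out 1 library unbalances the clones between groups. The shifts therefore mix the difference between the clones with the auxin change. The immediate early genes, which respond within minutes to growth stimuli, lay above 0 in 11 of 11 members (median 0.29, camera adjusted p = 0.000650, adjusted p = 0.922 with an estimated correlation). The feedback genes of EGF and FGF signalling through ERK, which restrain the growth factor pathway, lay above 0 in 10 of 12 (median 0.35, adjusted p = 0.0188, adjusted p = 0.922 with an estimated correlation). In both lists 0 members were called, over all genes tested and adjusted over the list alone. The immediate early list was not called without the 24 h library of clone 30 (median 0.27, adjusted p = 0.0792), and its median was 0.52 without that of clone 31 and 0.46 without the untreated library of clone 30. The feedback list was not called without the 24 h library of clone 30 (median 0.21, adjusted p = 0.152) or the untreated library of clone 30 (0.17, 0.695). With the clone as a block 3 more lists passed at 24 h, each with 0 members called, over all genes tested and adjusted over the list alone. They were mesenchymal markers (median -0.33, adjusted p = 0.0153), hypoxia targets (-0.62, 0.0153) and cholesterol synthesis genes (0.13, 0.0298), each with adjusted p = 0.944 with an estimated correlation. Within clones 30 and 31 the medians were -0.38 and -0.28 (mesenchymal), -0.80 and -0.19 (hypoxia) and 0.10 and 0.15 (cholesterol). These medians moved when single libraries were left out, again in fits without a clone term. On treatment group alone the mesenchymal median (-0.30) was 1.33 without the untreated library of clone 31 and 0.42 without the 24 h library of clone 30, and -1.27 without that of clone 31 (called, adjusted p = 0.00198). The hypoxia median (-0.47) was -0.17, -0.03 and -1.09 without the same libraries (the last called, 0.000566). Both lists were also called without the untreated library of clone 30 (0.0130 and 0.0136), and hypoxia without either 48 h library (8.07e-05 and 7.96e-05). The cholesterol median (0.12) was 0.77 without the untreated library of clone 31 and 0.56 without the 24 h library of clone 30 but -0.31 without the untreated library of clone 30 and -0.495 without the 24 h library of clone 31 (each called, adjusted p = 3.99e-05 to 0.0136).

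The comparison of 48 h of auxin with untreated cells asks what follows longer exposure. Genes that prepare and carry out DNA replication fell in both clones with the clone as a block. Ccne2, a cyclin that drives entry into S phase, went from 54.2 ± 10.7 to 19.8 ± 2.23 CPM (SD, n = 2; log2 -1.45 ± 0.11), and Cdc6, which loads the replicative helicase, fell by 1.30 ± 0.13. Mcm3 and Mcm4, subunits of that helicase, fell by 1.07 ± 0.12 and 0.89 ± 0.11 (edgeR adjusted p = 0.0238 for each of the 4 genes with the block, 0.139 to 0.146 without it). Of the S-phase list 14 of 14 genes fell and 0 rose over all genes tested and also adjusted over the list alone, with a median of -0.88 (-0.78 in clone 30, -0.88 in clone 31). Of the mitosis list 2 of 14 fell (Bub1 by 0.43 and Cdk1 by 0.44), or 6 adjusted over the list alone, and 0 rose. Within clones 30 and 31 the mitosis median was -0.315 and -0.191. On treatment group alone (-0.255) it was -0.02 without the 48 h library of clone 30 and -0.05 without the untreated library of clone 31. It was -0.51 without the 48 h library of clone 31 and -0.44 without the untreated library of clone 30. As at 24 h, these fits hold no clone term, so the shifts mix the difference between the clones with the auxin change. The same holds for the other list medians at 48 h on treatment group alone with 1 library left out.

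Of the targets and partners of the Notch pathway, which keeps neural progenitors undifferentiated, 6 of 14 rose at 48 h in the blocked fit, 0 fell and 8 were not called. Hes5, a repressor that is a main Notch output in NPCs (chromosome 4, 154960923 to 154962371), went from 4.38 ± 5.10 to 38.4 ± 8.23 CPM (log2 3.57 ± 0.81, edgeR adjusted p = 0.0387 with the block, 0.187 without). The feedback gene Nrarp rose by 2.16 ± 0.26, the ligand gene Dll1 by 1.66 ± 0.32, the target Hey1 by 1.53 ± 0.25 and Dtx4 by 0.94 ± 0.11. Adjusted over the list alone 8 rose (median 0.75). Without the untreated library of clone 30 the Notch median on treatment group alone went from 0.75 to 1.165. The NPC identity genes that rose were Sox9 (1.16 ± 0.15), Sox2 (1.03 ± 0.14), Sox3 (0.98 ± 0.15) and the growth factor receptor gene Egfr (0.87 ± 0.12). These 4 of 16 members rose and 0 fell, against 9 that rose and 1 that fell adjusted over the list alone (median 0.40). Within clones 30 and 31 the NPC median was 0.23 and 0.61. Without the untreated library of clone 31 the NPC median on treatment group alone went from 0.39 to 0.17, in a fit without a clone term.

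Some markers of glial cells also rose at 48 h in the blocked fit. The oligodendrocyte precursor receptor gene Pdgfra went from 0.756 ± 0.275 to 3.59 ± 1.32 CPM (SD, n = 2) and the myelin-associated gene Cnp from 105 ± 32.4 to 349 ± 156 CPM. Of the oligodendrocyte list 3 of 7 members rose and 0 fell, with the same counts adjusted over the list alone (median 1.51, with 0.58 in clone 30 and 2.09 in clone 31). Without the 48 h library of clone 31 its median on treatment group alone went from 1.536 to 0.805. The astrocyte list had 6 of 11 members that rose and 1 that fell, or 9 and 1 adjusted over the list alone (median 0.96). The transporter gene Slc4a4 rose by 1.11 ± 0.17, the calcium-binding gene S100b by 0.96 ± 0.18, the enzyme gene Aldoc by 0.97 ± 0.21 and the filament gene Gfap by 1.85 ± 0.28 from 0.499 CPM. Of 9 interferon response genes 4 rose and 0 fell, with the same counts adjusted over the list alone (median 0.74): the RNA sensors Ddx58 (0.74 ± 0.15) and Ifih1 (0.95 ± 0.24), Ifi27 (0.74 ± 0.16), and Oasl2. Oasl2 had 21 counts at 48 h against 2 untreated, a ratio of 11.9 (95% exact interval 2.91 to 105).

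Of the 12 feedback genes of EGF and FGF signalling 3 fell at 48 h in the blocked fit, 0 rose and 9 were not called, with Dusp4, a phosphatase that switches off ERK, at -2.36 ± 0.44, Ier3 at -1.65 ± 0.32 and the ERK-responsive factor Etv5 at -1.15 ± 0.25. Adjusted over the list alone 9 fell (median -0.97, with -0.44 in clone 30 and -1.59 in clone 31). The median on treatment group alone (-0.94) was -1.425 without the 48 h library of clone 30 and -0.61 without that of clone 31. The largest falls included Clic5, a chloride channel family gene (39.9 ± 21.3 to 2.89 ± 0.607 CPM, SD, n = 2; log2 -3.74 ± 0.32) and Dusp4. Close to them were the neural transcription factor gene Pou3f1 (-2.47), the exchange factor gene Rapgef5 (-2.42) and the muscarinic receptor gene Chrm3 (-2.38). Sertm1, the peptide hormone gene Apln, the synaptic gene Nptx1, Rflnb and the proteoglycan enzyme gene Chsy3 fell by 2.34, 2.32, 2.22, 2.10 and 2.07. Beside Hes5 the largest rises included Cyp4f15 (2.79), the differentiation inhibitor gene Id4 (2.77), the reticulophagy gene Retreg1 (2.60), and the channel gene Ttyh1 (2.56). They were followed by the kinase gene Tec (2.56), Ppp2r2b (2.45), the chemokine receptor gene Cxcr4 (2.42) and the kinase gene Camk2a (2.34).

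**Figure D2:**
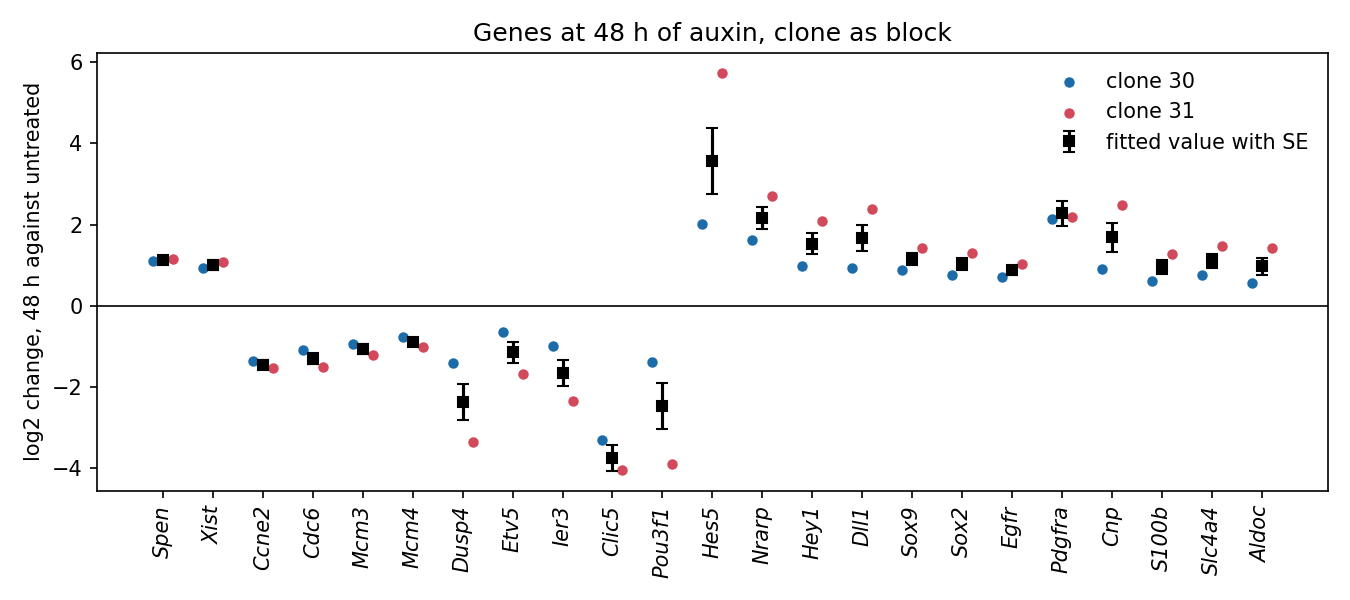
Log2 change at 48 h of auxin against untreated for Spen, Xist and 21 further genes. It has squares for the edgeR value with the clone as a block, bars for its standard error, and a blue and a red point for clones 30 and 31. The plotted replication genes lie below 0 in both clones and the plotted Notch, NPC and glial genes above 0 in both. The 21 genes were called in the blocked fit and chosen by p or size of change, which favours agreement between the clones. In the whole lists 1 of 14 Notch, 3 of 16 NPC and 2 of 11 astrocyte genes lay below 0 in that fit.

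At 48 h 2790 of 16007 genes passed with the clone as a block (1336 higher, 1454 lower); upper-quartile scaling gave 1524 higher and 1232 lower. On treatment group alone edgeR called 0 (3311 at an unadjusted p under 0.05), DESeq2 called 1669 and limma voom 0, so with this filter each rise and fall named here is called by edgeR in the blocked fit only. With no filter beyond 1 count edgeR on treatment group alone called 216 genes, among them Spen, Xist, Ccne2, Mcm3, Mcm4, Hey1, Sox9, Sox2, Egfr, S100b, Clic5, Apln, Rflnb and Chsy3 (adjusted p = 0.0232 to 0.0459). Without the untreated library of clone 31 the blocked count was 6, without the 24 h libraries of clones 30 and 31 it was 614 and 646, and without the 48 h library of clone 30 it was 6615. With the 4 libraries of these groups alone 3 genes passed. Camera called 7 lists on treatment group alone, and none was called with an estimated correlation. These were S phase (adjusted p = 8.58e-12, adjusted p = 0.441 with an estimated correlation), EGF and FGF feedback (2.64e-06, 0.497) and Notch (5.19e-06, 0.441). The others, with the same 2 values each, were NPC identity (0.000559, 0.441), oligodendrocyte (0.000559, 0.441), astrocyte (0.00650, 0.441) and interferon (0.0220, 0.441). With the block the mitosis list passed too (0.0432, with adjusted p = 0.773 with an estimated correlation). The interferon list (median 0.73 on treatment group alone) was not called without the untreated library of clone 31 (median 0.63) or the 48 h library of clone 30 (0.45). Those fits hold no clone term, and within clones 30 and 31 the interferon median was 0.67 and 0.70.

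**Figure D3:**
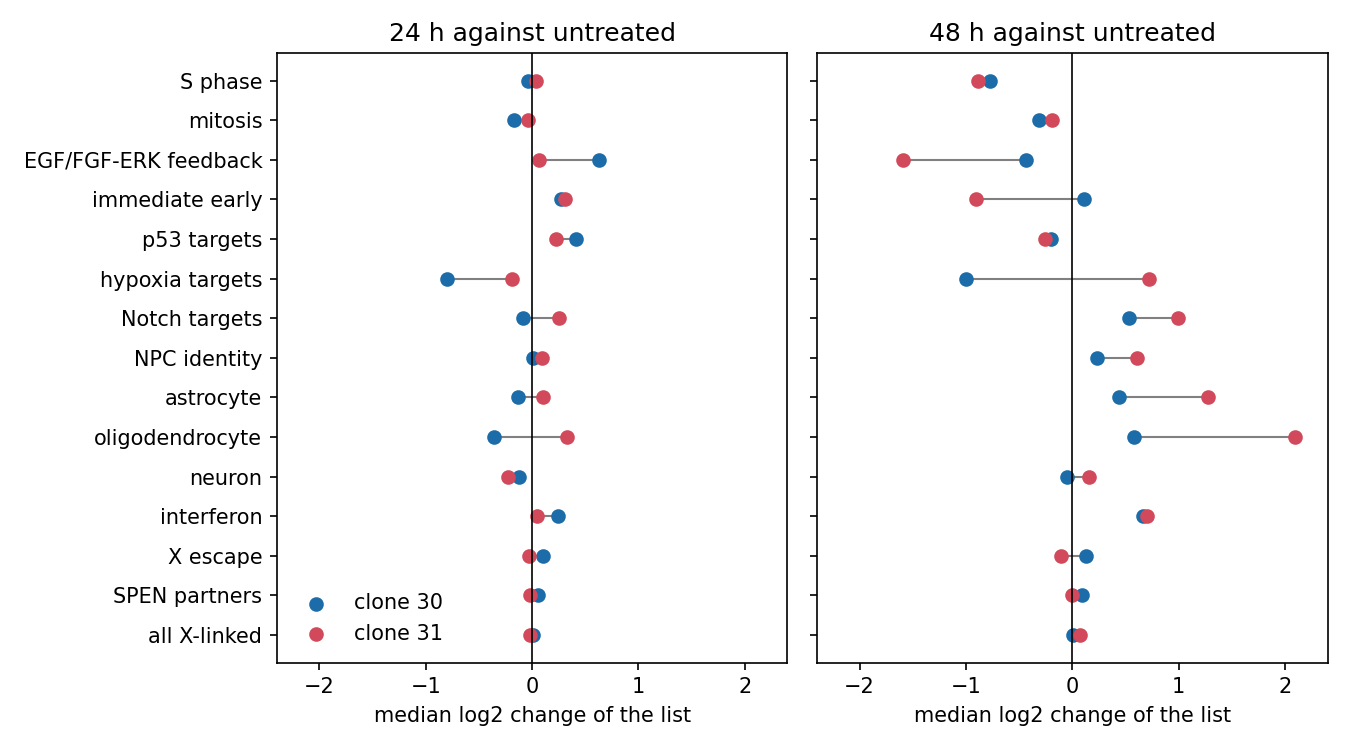
Median log2 change of the members of 15 gene lists at 24 h (left) and 48 h (right) against untreated, with blue points for clone 30, red points for clone 31 and a grey line between them. At 48 h the S-phase list lies at -0.78 and -0.88 in the clones, and the hypoxia list at -1.0 in clone 30 and 0.72 in clone 31.

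The direct comparison of 48 h with 24 h of auxin asks which genes separate the time points. Draxin, an axon guidance gene, went from 7.78 ± 7.54 to 94.9 ± 97.1 CPM (SD, n = 2; log2 3.52 ± 0.54 in the blocked fit). The water channel gene Aqp4, made by astrocytes, went from 2.17 ± 1.35 to 19.1 ± 2.48 CPM. Retreg1, Hes5 and Id4 rose by 3.56, 3.51 and 3.48. The neuronal activity gene Arc (93.5 ± 55.2 to 7.56 ± 4.30 CPM), the ERK feedback genes Spry4 and Dusp4, Clic5 and Pou3f1 fell by 3.34, 3.03, 2.81, 3.71 and 2.67. For these 10 genes the edgeR adjusted p ran from 0.0162 to 0.0362 with the block and from 0.0860 to 0.353 without it. All 14 S-phase genes fell, over all genes tested and adjusted over the list alone, and none rose (median -0.87), and 10 of 14 p53 targets fell and 0 rose, also 10 adjusted over the list alone (median -0.54).

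Between 24 h and 48 h 4185 genes passed with the block (1961 higher, 2224 lower); upper-quartile scaling gave 2549 higher and 1726 lower. On treatment group alone edgeR called 0 (3997 unadjusted), DESeq2 2530 and limma voom 0. The blocked count was 0 without the 24 h library of clone 30, 3 without that of clone 31 and 7449 without the 48 h library of clone 30. Camera called the S-phase (adjusted p = 1.54e-09, adjusted p = 0.506 with an estimated correlation), EGF and FGF feedback (1.85e-07, 0.506), Notch (0.000796, 0.506), oligodendrocyte (0.00113, 0.506), NPC identity (0.00355, 0.506), p53 (0.00355, 0.829) and astrocyte lists (0.0157, 0.506). The p53 list was not called without the 24 h library of clone 30 (median -0.21) or the 48 h library of clone 31 (-0.30). Its median on treatment group alone (-0.53) was -0.92 without the 24 h library of clone 31 and -0.98 without the 48 h library of clone 30. Within clones 30 and 31 it was -0.59 and -0.575. List medians with 1 library left out come from fits without a clone term here too. Their shifts mix the difference between the clones with the change between times. With the block the stress response list (median -0.49, adjusted p = 0.0321) and the cholesterol list (-0.19, 0.0340) passed too, with adjusted p = 0.614 and 0.727 with an estimated correlation. The cholesterol median on treatment group alone (-0.12) was 0.44 without the 24 h library of clone 31 and 0.375 without the 48 h library of clone 30, and -1.03 without that of clone 31 and -0.54 without the 24 h library of clone 30 (both called, 0.00476 and 0.0189). The stress median (-0.49) was -0.09 without the 24 h library of clone 31, and the list was called without the 24 h library of clone 30 (0.0107) or the 48 h library of clone 31 (0.0324). In each list 5 of 14 genes fell and 0 rose, with the same counts adjusted over the list alone. Of the feedback list 9 of 12 fell (11 adjusted over the list alone). Its median on treatment group alone (-1.01) was -1.54 without the 48 h library of clone 30 and -0.63 without that of clone 31. Of the Notch list 8 of 14 rose (8 rose and 1 fell adjusted over the list alone). Of the oligodendrocyte list 5 of 7 rose (also 5 adjusted over the list alone). Of the NPC list 7 of 16 rose and 1 fell (8 and 1 adjusted over the list alone), and of the astrocyte list 7 of 11 rose and 1 fell (9 and 1 adjusted over the list alone). In lists that camera did not call between times, the block called members over all genes tested where treatment group alone called 0. Those that rose and fell were 2 and 3 escape genes, 1 and 5 immediate early genes, 2 and 1 neuron markers, 2 and 2 receptor targets, 2 and 1 imprinted genes, and 1 and 1 of both the mesenchymal and the pluripotency markers. In addition 4 interferon genes and 1 gene each of the X-inactivation centre, SPEN partner and endoderm lists rose, and 2 hypoxia targets and 1 mitosis gene fell.

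The series title concerns X inactivation, so X-linked genes were set against autosomal genes. The median log2 change of 554 X-linked genes was -0.01 at 24 h and 0.04 at 48 h, beside 0.01 and 0.02 for autosomal genes. Between 24 h and 48 h it was 0.07 beside 0.03, and limma's camera gave an adjusted p of 0.603 in each of the 3 comparisons. Leaving out the escape genes and the X-inactivation centre, 535 X-linked genes gave -0.01, 0.04 and 0.07. Between the clones 537 X-linked genes had a median of 0.003 and a mean of -0.03, of opposite sign, and were not called (camera adjusted p = 0.833). At 48 h in the blocked fit 7.6% of X-linked and 8.4% of autosomal genes were higher (2-sided Fisher's exact test, p = 0.584, adjusted 0.701) and 6.7% and 9.2% were lower (p = 0.0499, adjusted 0.150, over 6 such tests). Between 24 h and 48 h the lower shares were 9.6% and 14.1% (Fisher's exact test, p = 0.00214, adjusted 0.0128), and the higher shares 11.7% and 12.3% (Fisher's exact test, p = 0.742, adjusted 0.742). These tests take genes as independent, which they are not, so their p-values do not measure the spread between clones. Among 15 escape genes, which stay active on the inactive X, the histone demethylase gene Kdm6a (0.39 ± 0.09) and the noncoding gene Firre (0.99 ± 0.23) rose at 48 h in the blocked fit. Utp14a and Pbdc1 fell by 0.57 and 0.45, and adjusted over the list alone 3 genes rose and 3 fell. The list's median was -0.02 and its mean 0.09, of opposite sign, and the list was not called (camera adjusted p = 0.951).

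Over both times together edgeR called 0 genes on treatment group alone (3064 unadjusted), DESeq2 2119 and the blocked fit 2832. The blocked count was 11 without the 24 h library of clone 30, 37 without that of clone 31 and 6930 without the 48 h library of clone 30. No gene was called at both 24 h and 48 h in edgeR, since none was called at 24 h. In DESeq2 with the block 16 of the 41 genes called at 24 h were also called at 48 h in the same direction, and 0 in the opposite one. Groups simulated without change against the same untreated libraries gave 1.4 on average over 10 simulations, from 8.4 calls at 24 h on average where 41 were observed. Independent lists would share 1.5 of the higher genes (6 observed) and 3.56 of the lower genes (10 observed). Part of that excess can come from the shared untreated libraries, which are too few to split. Across genes, which are not independent replicates, the log2 changes at 24 h and 48 h correlated at 0.05, against 0.51 in the simulations, with a covariance of 0.010 against 0.041. The simulated groups held no change at 48 h, so these 2 correlations cannot be compared directly. The simulated covariance was the larger, so the simulations may not match the spread of these libraries. The simulated 1.4 is therefore a rough guide only.

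The clones were compared over all times, with treatment group as a term, to show how the 2 subclones differ. The 14 genes of the cholesterol synthesis list were all higher in clone 31, over all genes tested and adjusted over the list alone (median log2 1.14). Lss, which encodes lanosterol synthase, stood at 101 ± 15.4 CPM in clone 30 and 347 ± 53.2 CPM in clone 31 (SD, n = 3; log2 1.77 ± 0.07, edgeR adjusted p = 0.000501). The pathway genes Fdps and Idi1 differed by 1.41 and 1.11. Target genes of p53 were lower in clone 31 in 12 of 14 cases and higher in 0, or 13 lower adjusted over the list alone (median -0.67). The death receptor gene Fas differed by -1.52 ± 0.13, the apoptosis gene Pmaip1 by -1.15 ± 0.10, Eda2r by -0.89 ± 0.09 and the stress gene Sesn2 by -0.75 ± 0.08. Mitosis genes were higher in 12 of 14 cases and lower in 0, also 12 adjusted over the list alone (median 0.42). They include the kinase genes Aurkb (0.63 ± 0.09) and Aurka (0.47 ± 0.07), the motor gene Kif11 (0.49 ± 0.07) and the proliferation marker Mki67 (0.55 ± 0.09). None of these 4 genes was called without the 24 h library of clone 30 (adjusted p = 0.0663, 0.130, 0.131 and 0.117) or of clone 31 (0.0673, 0.129, 0.127 and 0.113).

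The largest differences between the clones were in single genes. The matrix genes Dcn, Lum and Col3a1 stood at 0.425 ± 0.154, 0.930 ± 0.206 and 1.07 ± 0.190 CPM in clone 30 and at 26.0 ± 2.89, 29.2 ± 3.06 and 30.3 ± 5.46 CPM in clone 31 (SD, n = 3). The muscle gene Mybpc1 and the endothelial gene Emcn were higher in clone 31 by 4.31 and 3.96. Armh4 (chromosome 14, 49675952 to 49783383) stood at 148 ± 2.18 CPM in clone 30 and 0.238 ± 0.102 CPM in clone 31. Pax7, a transcription factor gene of dorsal neural tube and muscle, had 1069 counts in clone 30 and 3 in clone 31, a ratio of 421 (95% exact interval 144 to 2040). The protease gene Mmp14, the signalling gene Rgs8 and Cul9, whose product binds p53, differed by -6.13, -5.72 and -5.16. Spen was 0.34 ± 0.07 higher in clone 31 (edgeR adjusted p = 0.0259), which was not called without the untreated library of clone 30 (0.0893) or 31 (0.0884) or the 24 h library of clone 30 (0.258) or 31 (0.250). Xist differed by 0.31 ± 0.10 (adjusted p = 0.0953; DESeq2 0.0337).

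Between the clones 2503 of 15492 genes passed in edgeR (1174 higher in clone 31, 1329 lower), with 910 and 1609 under scaling by total counts alone. The count was 701 and 696 without the 24 h library of clone 30 and 31, 4927 and 4978 without the 48 h library of clone 30 and 31, and 566 without the treatment term. Of the mesenchymal list 5 of 9 were higher and 1 lower (6 and 1 adjusted over the list alone, median 2.04), with the matrix gene Postn at 2.04 ± 0.26 (not called without the 24 h library of clone 31, adjusted p = 0.0510). Of the neuron list 6 of 13 were lower and 1 higher (8 and 3 adjusted over the list alone, median -0.81). Neurod1, a neurogenic factor gene, differed by -3.03, the growth cone gene Gap43 by -1.12 and the filament gene Nefm by -1.58, while the vesicle gene Syt1 differed by 3.09. Camera also called the S-phase list (7 of 14 higher and 0 lower, or 10 and 1 adjusted over the list alone, median 0.31) and the stress list (5 of 14 higher and 0 lower, or 6 and 0 adjusted over the list alone, median 0.31). In the oligodendrocyte list, also called, 1 of 6 was higher and 1 lower, or 2 and 1 adjusted over the list alone (median 0.80, with 0.248 and 0.245 without the 48 h library of clone 30 and 31), and the proteoglycan gene Cspg4 was higher by 2.79. Camera adjusted p was 2.01e-30 for cholesterol, 7.17e-19 for mesenchymal, 1.08e-09 for p53, 1.50e-05 for mitosis and 0.00227 for each of the S-phase, stress, neuron and oligodendrocyte lists. With an estimated correlation none passed, with adjusted p = 0.368 with an estimated correlation for the cholesterol, mesenchymal and p53 lists, 0.391 for stress, 0.627 for mitosis, neuron and oligodendrocyte and 0.649 for S phase. Without the treatment term the S-phase list was not called (0.0766), nor were Spen (0.746), Pmaip1 (0.0596), Sesn2 (0.121), Syt1 (0.146), Pdgfrb (0.0544), Acta2 (0.0656), Aurkb (0.0603), Aurka (0.106), Kif11 (0.0711) and Mki67 (0.0530).

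**Figure D4:**
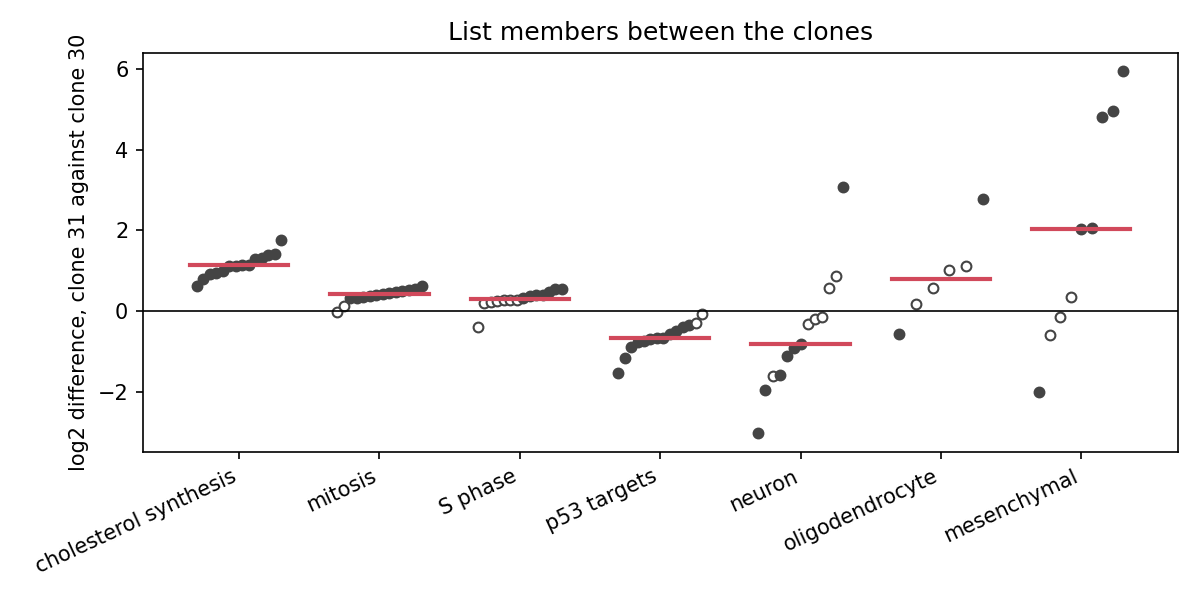
Log2 difference of clone 31 against clone 30 for each member of 7 gene lists, with filled points for genes past an adjusted p of 0.05 in edgeR, open points for the others, and red bars at list medians. Cholesterol genes all lie above 0 (median 1.14), and p53 targets all lie below 0 (median -0.67).

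Apart from the escape genes, 7 lists were called by camera in no comparison, in edgeR on treatment group alone or with the clone as a block, and are given by their median log2 change at 48 h on treatment group alone. The partners of SPEN, proteins of its repressor complexes, had a median of 0.00 over 11 genes (adjusted p = 0.966) and the X-inactivation centre 0.16 over 7 (0.408). Imprinted genes had 0.06 over 12 (0.996). The aryl hydrocarbon receptor targets, which indoles such as auxin can induce, had 0.29 over 5 with a mean of -0.20 of opposite sign (0.921). Pluripotency markers had 0.70 over 4 (0.532), endoderm markers 0.55 over 3 (0.506) and germline genes 0.45 over 2 (0.758). In the clone comparison the hypoxia, immediate early and feedback lists had medians of 1.05, -0.49 and -0.16 and were not called (adjusted p = 0.260, 0.0906 and 0.587). The hypoxia list was called between the clones without the untreated library of clone 30 (median 1.71, adjusted p = 0.000247) or 31 (1.71, 0.000602) and without the treatment term (0.00303). Its median was 0.62 without the 48 h library of either clone. On treatment group alone 0 members of these 7 lists were called over all genes tested at 48 h. Adjusted over the list alone, Xist, 1 pluripotency marker, 1 endoderm marker and 2 imprinted genes rose, and 1 endoderm marker, 1 receptor target and 2 imprinted genes fell. With the clone as a block Xist, 1 pluripotency marker, the endoderm marker Cxcr4, 1 receptor target and 2 imprinted genes rose over all genes tested, and 2 receptor targets and 2 imprinted genes fell. In other lists that camera did not call at 48 h the block called 3 p53 targets, 4 stress genes, 2 cholesterol genes and 2 hypoxia targets lower and 0 higher. It called 2 neuron markers higher and 1 lower, and 1 higher and 1 lower in both the mesenchymal and the immediate early list, where treatment group alone called 0. The p-values measure only the spread between these libraries, 2 subclones of a single hybrid background.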

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

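All tests on the 48 h changes and on Spen and Xist, and the tests on chromosomes and on fibroblast-like cells, were chosen after the results were seen; the count of other splits was planned.

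The hypoxia target list moved in opposite directions in the 2 clones at 48 h: its median log2 change was -1.0 in clone 30 and 0.72 in clone 31. Of 11 members 9 were lower in clone 30 and higher in clone 31, among them Pdk1 (-1.37 and 1.76), Bnip3 (-1.30 and 1.69) and Vegfa (-0.84 and 1.20). In clone 30 10 of the 11 were already lower at 24 h, when the medians were -0.80 in clone 30 and -0.19 in clone 31. From 24 h to 48 h the medians were -0.37 in clone 30 and 1.105 in clone 31. The falls in clone 30 at both times rest on its 1 untreated library. Lists of at least 5 members whose clone medians had opposite signs and lay at least 0.5 from 0 were picked out. Each clone has 1 library per time, so the difference between the clones was not tested, and no explanation was tested for it.

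The 2790 genes called at 48 h with the clone as a block were weighed against depth, GC content and culture state. Thinning every library to the lowest total left 2876 calls (2629 shared), and removing each library's trend on GC content and length left 2764 (2574 shared), which argues against either as the whole cause. The state of the culture at harvest cannot be told apart from auxin time, since no untreated library is labelled as kept for 48 h. The labels used here give hours of auxin, not hours in culture. Feedback genes of EGF and FGF signalling had a median of -0.97 and S-phase genes one of -0.88, so medium use or density at harvest may contribute. Loss of SPEN stays open as well, and no group of auxin-treated cells without the degron was analysed here.

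The higher Spen and Xist RNA at 48 h was weighed against scaling and against the broader change at 48 h. The smallest log2 change over 5 scalings was 1.13 for Spen and 1.0 for Xist, each more than 2 standard errors above 0, so scaling is unlikely to be the cause. Spen was already 0.91 ± 0.08 higher at 24 h, when the S-phase list had a median of -0.01. This argues against the change that the S-phase list follows as the source of Spen's rise. Other lists, among them p53 targets and immediate early genes, passed camera at 24 h with the preset correlation. An effect of auxin or culture that starts by 24 h therefore stays open. Xist was 0.49 ± 0.12 higher at 24 h, close to the midpoint of its 48 h change, so for Xist the test cannot decide on 2 clones. A direct effect of SPEN loss on either RNA may exist but stays a hypothesis.

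The 2503 genes that differed between the clones were weighed against the split itself, chromosome number and cell mixture. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one, and the highest other split gave 0. So few splits cannot give a share under 0.1. The other splits also leave the clone difference in the residual spread, so their counts do not show what splits without a clone effect would give. The chromosome median farthest from 0 was -0.041 (chromosome 13), which argues against gain or loss of a whole chromosome. Fibroblast-like cells in clone 31 cannot be told apart from expression by the NPCs themselves for Col3a1, Lum and Dcn, since the other 6 members of the mesenchymal list went both ways (median difference 0.10). Pdgfrb (2.05) and Postn (2.04) were called higher in clone 31 and Acta2 (-2.01) lower, the last not without either 24 h library (adjusted p = 0.0928 and 0.0908). Without the treatment term neither Pdgfrb (0.0544) nor Acta2 (0.0656) was called. Thy1 (0.34), Col1a1 (-0.14) and Tagln (-0.59) were not called. Heritable differences between subclones remain open and were not tested.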

How the results depend on the processing

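The replicate block, DESeq2 and the filter moved the counts. With no filter beyond 1 count edgeR on treatment group alone called 216 genes at 48 h, 833 between 24 h and 48 h and 374 at any time, in place of 0 each. DESeq2 called 6 at 24 h, 1669 at 48 h, 2530 between times and 2119 at any time. With the clone as replicate block edgeR called 2790, 4185 and 2832, and 0 at 24 h; among the results reported the block changed no other call than those given beside them. The block takes the average difference between the clones out of the spread, which was lower with it (0.121 against 0.271), on 2 residual degrees of freedom in place of 3. Why DESeq2 and the filter moved the counts was not tested. Between the clones 2503 became 566 without the treatment term. In the blocked fits DESeq2 gave 41 at 24 h, and the 4 libraries of the groups compared (chosen after the data were seen) gave 140 at 24 h and 3 at 48 h, on fewer libraries.

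Leaving out 1 library gave 0 to 263 genes at 24 h, 6 to 6615 at 48 h, 0 to 7449 between times and 11 to 6930 at any time with the block, and 696 to 4978 between the clones. The lone sample left in a group is then assumed to vary like the other groups. Size factors, scaling, a 1 CPM filter, limma voom, thinning and GC correction kept each blocked count at 48 h and between times within 1.5-fold.

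Lists called fell to 0 in every comparison with an estimated correlation, and to 0 at 24 h, at 48 h and between times with fry, which asks another question. With the block 6 lists passed at 24 h in place of 3. Leaving out 1 library gave 4 to 10 at 24 h and 7 to 11 between times. The p53 list at 24 h ranged from -0.031 to 0.679, below 0 without the 24 h library of clone 30. The cholesterol list at 24 h ranged from -0.495 to 0.770, with -0.306 without the untreated library of clone 30. The ends of both ranges come from fits without a clone term, so they mix the difference between the clones with the auxin change. Camera called X-linked genes under no alternative.

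Of the named genes no direction was counted as reversed. A change of sign counted as reversed only where the main or the alternative fit called the gene, and otherwise as no change. Changes of sign without a call were therefore not followed for the named genes. At 24 h 4 of their alternative results gained a call (446 did not change), at 48 h 106 (671), between times 21 (159); between the clones 1 gained and 26 lost one (446). In the auxin comparisons the alternatives were set against treatment group alone, which called 0 genes, so no call could be lost there. Calls made with the block were not followed gene by gene when 1 library was left out. The 4 libraries cannot be run for the clone or any-time tests. Thinning to the lowest total left 2876 calls at 48 h in the blocked fit, which argues against unequal depth as the source of that count. Thinning was not run for the clones or on treatment group alone, and what greater depth would add was not tested.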

Other observations

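The test on genomic span and the one on neurons were chosen after the 24 h genes were seen; the one on GC content and length was set before its result was known.

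Long genes may be lower at 24 h as a class. Of 23 protein-coding genes that DESeq2 with the block called lower at 24 h, 12 span at least 300 kb (52.2%), against 3.3% of the 13392 protein-coding genes tested (Fisher's exact test, p = 1.52e-12); of 12 called higher 0 do. The 445 long genes had a median log2 change of -0.11 in clone 30 and -0.20 in clone 31, beside 0.02 in both for lists matched on expression. Each lay at percentile 0.01 of 10000 such lists, the smallest they can give; at 48 h the medians were -0.02 and -0.12, at percentiles 3.17 and 0.01. Camera in the blocked fit gave p = 4.39e-18 with the preset and p = 0.0384 with an estimated correlation at 24 h, and p = 0.180 and p = 0.560 at 48 h. Removing the trend on GC content and exon length left the long genes -0.20 below the others (-0.17 before it), which argues against that trend as the cause. Fewer neurons at 24 h cannot be told apart from this, since the neuron list had a median of -0.16 with 8 of 14 members below 0 and 6 above, and many long genes are neuronal. A pattern found and tested on the same 4 libraries is a hypothesis.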
